A study of Oryza sativa with 24 samples.

How the data were processed

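The series measured RNA of rice anthers by sequencing. It held 24 libraries from 4 lines (Nipponbare, Sasanishiki, PL9 and Lambayeque1), each grown untreated or exposed to 12 °C for 4 days, with 3 libraries in each of the 8 groups. Per the labels' protocols, plants stood 20 to a pot in a greenhouse at 25 °C by day and 19 °C by night. The titles number 3 libraries per group, and the groups and numbers were taken from them. The series text speaks of 2 replicates, and nothing in the labels settles which is meant, so each n of 3 rests on the titles. Nothing in the labels says that the libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

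The deposited files hold 1 signal value per row, named TPM in the file headers. Per the submitters' processing notes, kallisto 0.46.2 and sleuth 0.30.0 were among the tools and IRGSP-1.0 was the genome build. The column totals were 1.20 to 1.72 times the fixed sum of a TPM column, copied rows included. With each identifier counted once, its repeated values read back, they were 0.86 to 1.36 times that sum. The deposited values were therefore treated as an abundance signal on a scale set by the authors. The median log2 ratio of a library to the mean library lay between -0.01 and 0.04. The files hold no read counts, so the depth of each library is unknown and no counting interval was computed.

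Each file has 44785 rows and 37910 identifiers, of which 32511 stand on 1 row. The other 5399 identifiers fill 12274 rows, up to 7 each. In all 5399 of them, the values fit 1 value per library repeated as often as the identifier has rows and written row by row across the libraries, line by line in the order Sasanishiki, Lambayeque1, PL9, Nipponbare. Values of 1 library thus stand in the columns of its neighbours, also across treatments and lines. On these rows 99.67% to 99.68% of the values above 0 in both were exactly equal in control libraries 1 and 2 of a line, against 0% of such values between libraries of a group on the rows that stand alone. The analysis was therefore restricted to identifiers on 1 row, a departure from the plan to sum the rows of each gene that was made after the files were seen and before any test. Reading the repeated values back into 1 value per library, and summing the rows as planned, were kept as alternatives. Of the 24 orders of lines tried, only the one given above fitted all 5399 identifiers. The next best order fitted 5359 and each other order 5154, so few identifiers tell the orders apart. The order of treatments and replicates was not varied in that check. A second check compared the correlations between libraries over read-back genes with those over genes on 1 row. All 276 exchanges of 2 libraries, 24 of them within a group, gave a worse match than the order used. The margin was small (0.9807 against at most 0.9796).

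Genes with a value of at least 1 in at least 3 libraries were tested, 22495 in all. Values were transformed as log2(value + 1), and all fold changes are on that scale, which understates the change of low genes. The 8 group means were fitted to all 24 libraries with limma 3.58.1 (lmFit, eBayes with a trend) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Comparisons were cold against control in each line, the average of these, the differences between lines in the response, and the differences between untreated lines. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. Tested on simulated data with 200 changed genes among 22495 in the Nipponbare comparison, the fit recovered 46.3% of log2 changes of 1, 85.1% of 2 and 95.5% of 4, and 3.21% of its calls were false. In the simulation the noise was normal and independent between genes and the lines had equal means. The changed genes had a mean log2 value above 2. These shares therefore need not hold for the real data.

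Gene lists were tested with limma's camera, with an inter-gene correlation preset at 0.01 and, beside it, estimated. Of the 23 lists, 13 were fixed before the data were examined, and the others were written after the files were opened and before any test. The reference table of gene symbols belongs to another assembly (ASM3414082v1) and holds no identifiers of the kind in the files, so it was used only for names, by chromosome and relative gene order within 2% of the chromosome's genes. By that check 93 members of the fixed lists agreed and 54 had names missing from the table. Another 4 were dropped because the table gives the name elsewhere, and 2 were not found in the files. The 54 without a checked name were kept in the fixed lists, so counts and tests of those lists include members of unchecked identity. In the lists written later 166 members agreed and were used. Gene descriptions were not used here, so members that were to be found by description were not added, and no coordinates are given.

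The genes named in the text follow a rule set before the data were examined, applied to genes whose name passed the check. Shared genes are those past the threshold in the same direction in 4 lines, with no overlap of cold and control libraries in any line and a mean of at least 10 in the higher group. Up to 12 per direction with the largest average change were to be named. For each line the 5 largest changes per direction were taken, and for each untreated pair the 2 largest, under the same conditions. The 10 smallest p-values of the test between lines and up to 4 members of each list follow. Beyond this rule, and after their values were seen, were chosen OsNCED3, SLR1 and CYP703A3 within their lists, OsC4, CYP703A3 and RAB16A in the test between lines, the examples for pairs of lines, and the identifiers without a checked name. Alternatives were other pseudocounts, filters, scalings and weights, a replicate block, fits on the compared groups alone, a fold minimum, and leaving out each library. After the data were seen, reading the repeated rows back and lists restricted to checked names were added, and summing the rows, the plan at first, became an alternative.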

Results

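The data are RNA abundances in anthers of 4 rice lines, each untreated or after 4 days at 12 °C, in 3 libraries per group. Between 17563 and 19303 identifiers on 1 row had a value of at least 1 per library. The depth of the libraries is unknown. The 20 most abundant identifiers took 9.6% to 18.5% of the total in untreated libraries and 19.1% to 27% in cold libraries. Libraries 1 and 2 of PL9 after cold had the lowest median correlations with their own group. For the PL9 cold libraries these were 0.905, 0.891 and 0.941 for libraries 1, 2 and 3, and library 2 had the lowest value of all libraries. Untreated anthers are the background for each cold value. When they were collected relative to the cold treatment is not stated in the labels.

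**Figure D1:**
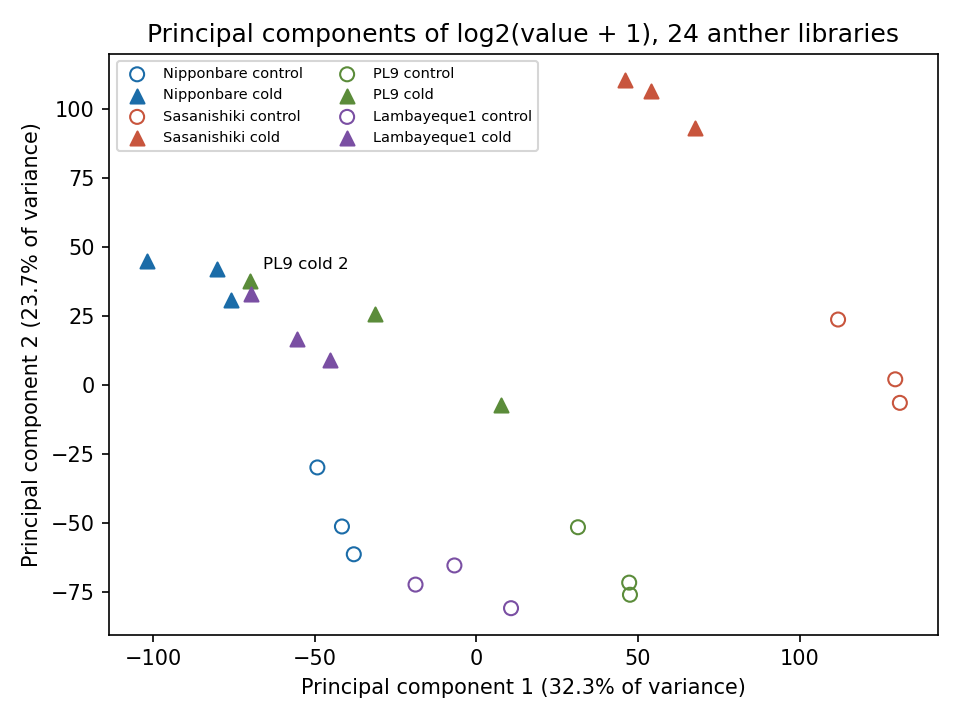
Principal components 1 and 2 of log2(value + 1) over the tested genes, with 32.3% and 23.7% of the variance, 1 point per library, open circles for untreated and filled triangles for cold libraries, and 1 colour per line. The PL9 cold libraries 1, 2 and 3 lie at 7.69, -69.93 and -31.47 on component 1.

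The first question was which genes changed with cold in all lines. Genes of the tapetum, the anther layer that feeds the pollen and supplies its wall, were among those that rose. The lipid transfer protein gene OsC4 (Os08g0546300) had an average log2 change of 8.0 (SE 0.42, adjusted p = 1.47e-10, n = 12 in each treatment). The aspartic protease gene OsAP25 (Os03g0186900) had an average log2 change of 6.06 (SE 0.66, adjusted p = 4.78e-07, n = 12 in each treatment). The cell wall invertase gene CIN2 (Os04g0413500) had an average log2 change of 3.60 (SE 0.26, adjusted p = 4.63e-09, n = 12 in each treatment). OsC6, another lipid transfer protein gene, EAT1, a tapetum transcription factor gene, and RAFTIN1 rose by log2 changes of 2.03, 1.57 and 1.14. The jasmonate receptor genes COI1B and COI1A and the starch debranching gene ISA1 rose by 1.40, 1.01 and 1.24. Other genes fell. The dehydrin gene RAB16A (Os11g0454300) had an average log2 change of -6.65 (SE 0.71, adjusted p = 3.74e-07, n = 12 in each treatment). The heat shock factor gene HSFB2B (Os08g0546800) had an average log2 change of -4.20 (SE 0.26, adjusted p = 5.72e-10, n = 12 in each treatment), and the protein phosphatase gene OsPP2C68 (Os09g0325700) had an average log2 change of -3.83 (SE 0.34, adjusted p = 4.44e-08, n = 12 in each treatment). HSP18.0, OsPP2C30, SNAC2 and HSFA3 fell too, with log2 changes of -3.52, -3.19, -2.80 and -1.76. These genes passed the test in the same direction in each line.

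In the list of pollen wall and tapetum products, 13 of 20 measured members rose, 1 fell and 6 did not pass the test (14 higher and 2 lower adjusted over the list alone). The list test gave adjusted p = 1.51e-04 with the preset and adjusted p = 0.407 with an estimated correlation. The rise went with a larger share of the most abundant identifiers in cold libraries, given above. OsC4, OsAP25 and CYP703A3, a fatty acid hydroxylase of the pollen wall, rose, the last by 4.37. The member that fell has no checked name. In the list of cold-protective proteins, 0 of 9 measured members rose, 9 fell and 0 did not pass the test (0 higher and 9 lower adjusted over the list alone). OsLti6a, RAB16B and SalT fell by 1.76, 3.16 and 1.78 on the log2 scale. The list test gave adjusted p = 6.43e-04 with the preset and adjusted p = 0.407 with an estimated correlation. In the abscisic acid list, 0 of 8 measured members rose, 8 fell and 0 did not pass the test (0 higher and 8 lower adjusted over the list alone). Its members include OsNCED3, of the synthesis of the hormone, which fell by 1.40. They also include OsABA8ox3, of its breakdown, which fell by 3.04, and the phosphatase genes above, which restrain its signal. The list test gave adjusted p = 7.00e-04 with the preset and adjusted p = 0.407 with an estimated correlation. Among cold-responsive transcription factors, 1 of 13 measured members rose, 5 fell and 7 did not pass the test (1 higher and 5 lower adjusted over the list alone). OsDREB1A, OsDREB1C and OsWRKY71 fell by 1.02, 1.60 and 3.03, and the member that rose has no checked name. The list test gave adjusted p = 0.281 with the preset and adjusted p = 0.815 with an estimated correlation, while with repeated rows read back 1 of 17 were higher and 8 lower (adjusted p = 0.0352 with the preset and 0.743 with an estimated correlation). Among tapetum regulators, 2 of 7 measured members rose, 0 fell and 5 did not pass the test (2 higher and 0 lower adjusted over the list alone). EAT1 and MSP1, a receptor kinase gene, rose by 1.57 and 0.95. The list test gave adjusted p = 0.159 with the preset and adjusted p = 0.561 with an estimated correlation. Within single lines, these regulators passed with the preset and not with an estimated correlation in Sasanishiki (3 higher, adjusted p = 0.0138 and 0.407) and PL9 (2 higher, adjusted p = 0.0292 and 0.407), with median log2 changes of 1.52 and 1.62. The medians were -0.25 in Nipponbare and -0.14 in Lambayeque1, where the direction of the list test was nonetheless upward (adjusted p = 0.896 and 0.951, and 0.782 and 0.896). No difference between lines was tested for lists. Cold-responsive transcription factors in Sasanishiki passed likewise (1 higher and 4 lower, adjusted p = 0.0352 and 0.598), as did meiosis genes in PL9 (0 higher and 2 lower, adjusted p = 0.0413 and 0.407).

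In the meiosis list, 1 of 7 measured members rose, 4 fell and 2 did not pass the test (1 higher and 4 lower adjusted over the list alone). OsDMC1A, a recombinase gene of meiosis, fell by 1.1, PAIR3 by 0.62 and OsSPO11-1 by 0.35, and MEL1 rose by 0.48. The test of meiosis gave adjusted p = 0.223 with the preset and adjusted p = 0.482 with an estimated correlation. In the gibberellin list, 2 of 10 measured members rose, 5 fell and 3 did not pass the test (2 higher and 5 lower adjusted over the list alone). OsCPS1, OsKO2 and OsKAO, of its synthesis, fell by 1.81, 0.66 and 1.27, and SLR1, which restrains its signal, rose by 0.48. Without a checked name, Os01g0177400, planned for this list as OsGA3ox2, rose by 2.85. Os01g0757200, planned as OsGA2ox3 and also unchecked, fell by 2.62. Both moved more than the genes just named, so the fall of those synthesis genes does not stand for the whole list. The test of gibberellin gave adjusted p = 0.315 with the preset and adjusted p = 0.653 with an estimated correlation. In the clock list, 2 of 4 measured members rose, 1 fell and 1 did not pass the test (2 higher and 1 lower adjusted over the list alone). OsLUX rose by 1.85 and OsPRR1 by 0.31. The member that fell, Os11g0157600, had the largest change of the list (-2.43) but no checked name. The test of circadian clock gave adjusted p = 0.931 with the preset and adjusted p = 0.958 with an estimated correlation, while with repeated rows read back 4 of 11 were higher and 4 lower. Among antioxidant enzymes, 2 of 7 measured members rose, 1 fell and 4 did not pass the test (2 higher and 1 lower adjusted over the list alone). OsAPX2 and SODA rose by 0.91 and 0.89, and Os04g0600300, without a checked name, fell by 1.30. The test of antioxidant enzymes gave adjusted p = 0.875 with the preset and adjusted p = 0.95 with an estimated correlation, while with repeated rows read back 2 of 10 were higher and 2 lower. In the list of anther sugar supply and pollen starch, 2 of 6 measured members rose, 1 fell and 3 did not pass the test (2 higher and 1 lower adjusted over the list alone). None of its members that moved has a checked name. Os04g0413500, planned for this list as OsINV4, was dropped at the name check and is not among the measured members. That gene is given above as CIN2, which rose in each line. The test of anther sugar supply and pollen starch gave adjusted p = 0.844 with the preset and adjusted p = 0.899 with an estimated correlation. Among stamen identity genes, 0 of 3 measured members rose, 1 fell and 2 did not pass the test (0 higher and 1 lower adjusted over the list alone). OsMADS2 fell by 0.46, and OsMADS16 had a log2 change of 0.10. The test of stamen identity gave adjusted p = 0.76 with the preset and adjusted p = 0.877 with an estimated correlation. Of markers of carpel and outer floret, which a dissected anther can carry along, 2 of 4 measured members rose, 1 fell and 1 did not pass the test (2 higher and 1 lower adjusted over the list alone). OsMADS6 and OsMADS13 rose by 0.70 and 0.42, and DL fell by 0.30. The test of carpel and outer floret markers gave adjusted p = 0.619 with the preset and adjusted p = 0.815 with an estimated correlation, while with repeated rows read back 2 of 6 were higher and 3 lower. The 1 measured MADS gene of maturing pollen rose by 0.82 (1 higher and 0 lower adjusted over the list alone), and was too few for a list test, while with repeated rows read back 1 of 3 were higher and 1 lower. The calls of OsPRR1 (lost in 21 settings), DL (lost in 18 settings) and OsKAO (lost in 15) depended on the setting. The median and the mean or the test differed in sign for the averaged clock list (median 0.10, mean -0.09), the antioxidant list (-0.02 and 0.03) and the sugar and starch list (median -0.09, test upward). Over all lists and comparisons, 28 of 110 list tests passed with the preset correlation and 0 with an estimated one, at an adjusted p of 0.407 or more. With treatments regrouped within lines, up to 23 passed with the preset, so the pass of a single list with it does not exclude chance.

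Identifiers without a checked name also changed in each line. Os01g0252300 and Os05g0342000 rose by 5.84 and 5.26, and Os01g0314800 and Os03g0168100 had log2 changes of -6.33 and -5.86. For the average over lines, 11373 of 22495 genes passed the adjusted threshold, 5720 higher and 5653 lower (5671 and 5718 with median-of-ratios rescaling). Of these, 2645 changed by a log2 fold of at least 1.

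**Figure D2:**
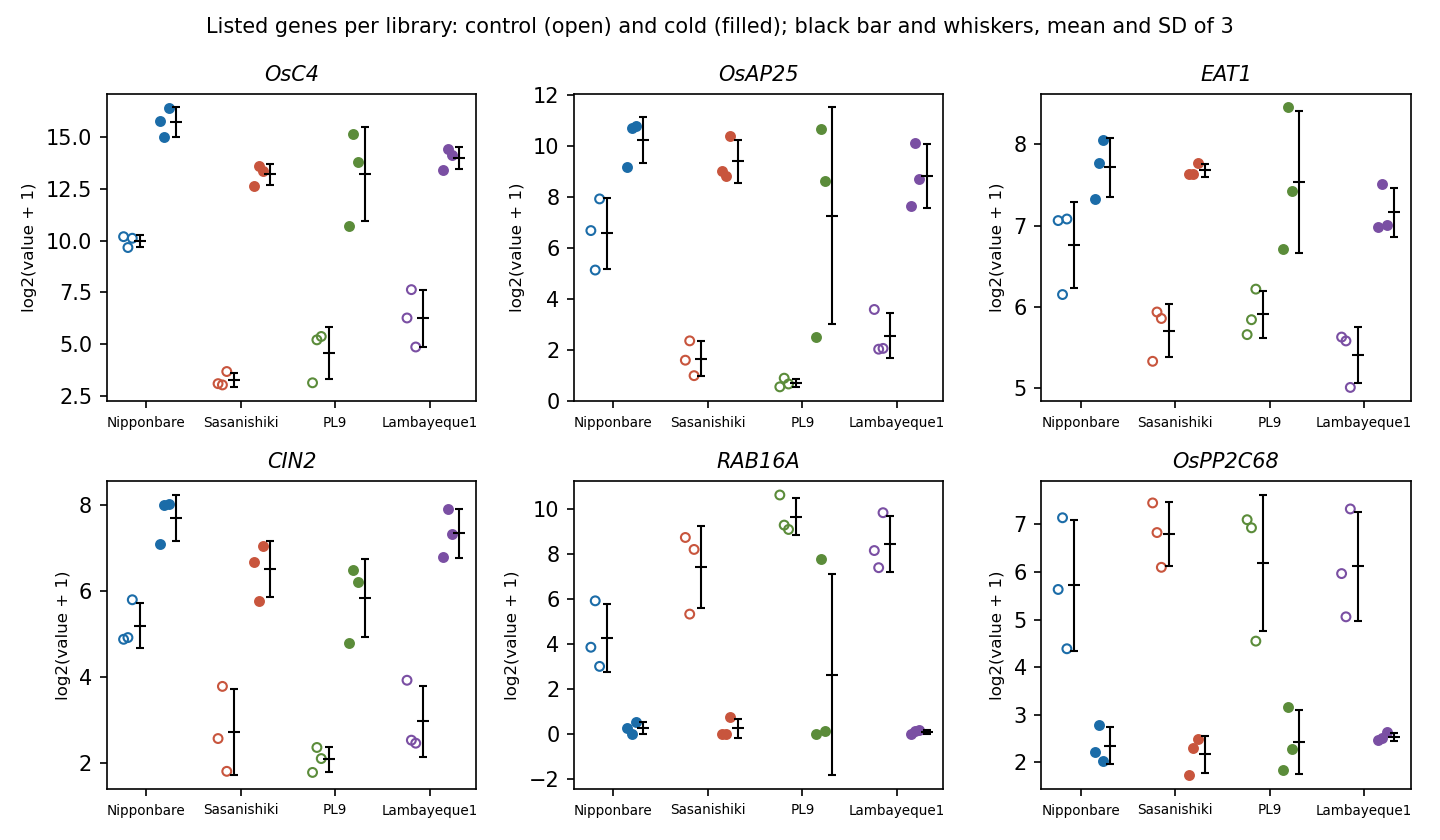
Values per library of OsC4, OsAP25, EAT1, CIN2, RAB16A and OsPP2C68 as log2(value + 1), open points for untreated and filled points for cold libraries of each line, with black bars and whiskers for the mean and SD of 3 libraries. In each line all cold libraries lie above the untreated ones for the first 4 genes and below them for RAB16A and OsPP2C68, with average log2 changes of 8.0 for OsC4 and -6.65 for RAB16A.

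In Nipponbare, the tapetum gene OsC4 (Os08g0546300) went from 1025 ± 189.7 to 57969 ± 27029 (SD, n = 3 in each), a log2 change of 5.73 (SE 0.84, adjusted p = 6.63e-05). OsLUX, a gene of the circadian clock, and PETE, which encodes plastocyanin, also rose. The log2 changes of the other named genes that rose were OsAP25 (3.65, SE 1.31, adjusted p = 0.0462), OsLUX (2.91, SE 0.45, adjusted p = 9.71e-05), CIN2 (2.51, SE 0.53, adjusted p = 0.00174) and PETE (2.34, SE 0.42, adjusted p = 4.02e-04). The named genes that fell were HSFB2B (-4.70, SE 0.51, adjusted p = 3.11e-06), RAB16A (-4.01, SE 1.41, adjusted p = 0.0418), OsPP2C68 (-3.37, SE 0.68, adjusted p = 0.00118), OsPP2C30 (-3.25, SE 0.76, adjusted p = 0.00384) and HSP18.0 (-3.24, SE 0.73, adjusted p = 0.00289). The pollen wall and tapetum products had 5 of 20 higher and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.0305 with the preset and adjusted p = 0.561 with an estimated correlation, while with repeated rows read back 5 of 22 were higher and 1 lower (adjusted p = 0.0664 with the preset and 0.743 with an estimated correlation)). The cold-protective proteins had 0 of 9 higher and 3 lower (0 and 4 adjusted over the list alone; adjusted p = 0.162 with the preset and adjusted p = 0.644 with an estimated correlation, while with repeated rows read back 0 of 13 were higher and 7 lower (adjusted p = 0.00543 with the preset and 0.531 with an estimated correlation)). The abscisic acid genes had 0 of 8 higher and 5 lower (0 and 6 adjusted over the list alone; adjusted p = 0.00462 with the preset and adjusted p = 0.449 with an estimated correlation). In Nipponbare, 5944 of 22495 genes passed the adjusted threshold, 2702 higher and 3242 lower (3311 and 2992 with quantile normalization), and 3178 had a log2 fold of at least 1. OsAP25 lost the call at adjusted p = 0.0575 with pseudocount 0.1, 0.0623 with no filter, 0.0656 with quantile normalization, 0.063 with the highest row per gene, 0.0629 with repeated rows summed, 0.0988 without Nipponbare control replicate 1, 0.168 without Nipponbare control replicate 2, 0.056 without Nipponbare cold replicate 1, 0.104 without Nipponbare cold replicate 2 and 0.127 without Nipponbare cold replicate 3, and RAB16A at 0.148 with pseudocount 5, 0.0567 with no filter, 0.0576 with the highest row per gene, 0.0551 with replicate block, 0.0575 with repeated rows summed, 0.0796 without Nipponbare control replicate 1, 0.161 without Nipponbare control replicate 2, 0.0923 without Nipponbare cold replicate 1, 0.086 without Nipponbare cold replicate 2 and 0.0824 without Nipponbare cold replicate 3.

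In Sasanishiki, the tapetum gene OsC4 (Os08g0546300) went from 8.83 ± 2.57 to 9677 ± 3081 (SD, n = 3 in each), a log2 change of 9.92 (SE 0.84, adjusted p = 3.94e-07). The pollen wall gene CYP703A3, a fatty acid hydroxylase of the tapetum, and the protease gene OsAP37 also rose. The log2 changes of the other named genes that rose were CYP703A3 (8.07, SE 1.47, adjusted p = 6.23e-04), OsAP25 (7.76, SE 1.31, adjusted p = 3.44e-04), OsAP37 (4.07, SE 1.25, adjusted p = 0.0219) and CIN2 (3.78, SE 0.53, adjusted p = 5.97e-05). The named genes that fell were RAB16A (-7.19, SE 1.41, adjusted p = 0.00115), OsPP2C68 (-4.62, SE 0.68, adjusted p = 9.58e-05), HSP16.9B (-4.55, SE 0.67, adjusted p = 9.98e-05), OsPP2C30 (-4.47, SE 0.76, adjusted p = 3.70e-04) and OsWRKY71 (-4.29, SE 0.83, adjusted p = 0.00102). The pollen wall and tapetum products had 14 of 20 higher and 1 lower (14 and 2 adjusted over the list alone; adjusted p = 6.00e-06 with the preset and adjusted p = 0.407 with an estimated correlation). The cold-protective proteins had 0 of 9 higher and 4 lower (0 and 7 adjusted over the list alone; adjusted p = 0.00339 with the preset and adjusted p = 0.407 with an estimated correlation). The abscisic acid genes had 0 of 8 higher and 5 lower (0 and 7 adjusted over the list alone; adjusted p = 6.43e-04 with the preset and adjusted p = 0.407 with an estimated correlation). In Sasanishiki, 5638 of 22495 genes passed the adjusted threshold, 2832 higher and 2806 lower (2760 and 2877 with median-of-ratios rescaling), and 3045 had a log2 fold of at least 1. The count was 3438 without Sasanishiki control replicate 1. OsAP37 lost the call at adjusted p = 0.0791 with pseudocount 5, 0.0686 without Sasanishiki control replicate 1, 0.0928 without Sasanishiki cold replicate 1 and 0.064 without Sasanishiki cold replicate 2.

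In PL9, the tapetum gene OsC4 (Os08g0546300) went from 28 ± 18 to 17134 ± 17167 (SD, n = 3 in each), a log2 change of 8.64 (SE 0.84, adjusted p = 1.01e-05). PETE, which encodes plastocyanin, and 4CL3, a gene of the phenylpropanoid pathway, also rose. The log2 changes of the other named genes that rose were OsAP25 (6.56, SE 1.31, adjusted p = 0.00253), CIN2 (3.75, SE 0.53, adjusted p = 1.87e-04), PETE (3.08, SE 0.42, adjusted p = 1.39e-04) and 4CL3 (2.09, SE 0.27, adjusted p = 9.53e-05). The named genes that fell were RAB16A (-7.04, SE 1.41, adjusted p = 0.00255), HSP17.4 (-4.26, SE 0.52, adjusted p = 7.70e-05), OsPP2C68 (-3.75, SE 0.68, adjusted p = 0.00125), HSFB2B (-3.50, SE 0.51, adjusted p = 2.48e-04) and HSP18.0 (-2.96, SE 0.73, adjusted p = 0.00995). The pollen wall and tapetum products had 12 of 20 higher and 1 lower (13 and 1 adjusted over the list alone; adjusted p = 6.00e-06 with the preset and adjusted p = 0.407 with an estimated correlation). The cold-protective proteins had 0 of 9 higher and 5 lower (0 and 5 adjusted over the list alone; adjusted p = 0.00152 with the preset and adjusted p = 0.407 with an estimated correlation). The abscisic acid genes had 0 of 8 higher and 3 lower (0 and 3 adjusted over the list alone; adjusted p = 0.0305 with the preset and adjusted p = 0.557 with an estimated correlation). In PL9, 3897 of 22495 genes passed the adjusted threshold, 2036 higher and 1861 lower (2049 and 2074 with quantile normalization), and 2212 had a log2 fold of at least 1. The count was 1811 without PL9 control replicate 1, 2217 without PL9 control replicate 2, 2095 without PL9 cold replicate 2, 2109 without PL9 cold replicate 3. RAB16A had values of 0, 224 and 0.098 in PL9 cold libraries 1, 2 and 3, and OsAP25 values of 4.61, 1607 and 389.8. OsAP25 lost the call at adjusted p = 0.093 with only the compared groups in the fit, and RAB16A at 0.0926 with only the compared groups in the fit, and HSP18.0 at 0.0523 without PL9 control replicate 1, 0.0509 without PL9 control replicate 2 and 0.0535 without PL9 cold replicate 2.

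In Lambayeque1, the tapetum gene OsC4 (Os08g0546300) went from 100.2 ± 87.1 to 16814 ± 5457 (SD, n = 3 in each), a log2 change of 7.73 (SE 0.84, adjusted p = 5.32e-06). The clock gene OsLUX and the lipid transfer gene OsC6 also rose. The log2 changes of the other named genes that rose were OsAP25 (6.27, SE 1.31, adjusted p = 0.00199), CIN2 (4.37, SE 0.53, adjusted p = 1.39e-05), OsLUX (3.29, SE 0.45, adjusted p = 4.18e-05) and OsC6 (2.74, SE 0.54, adjusted p = 0.00132). The named genes that fell were RAB16A (-8.38, SE 1.41, adjusted p = 3.31e-04), HSFB2B (-5.97, SE 0.51, adjusted p = 4.81e-07), HSP17.4 (-5.08, SE 0.52, adjusted p = 2.99e-06), HSP18.0 (-4.74, SE 0.73, adjusted p = 1.42e-04) and RAB16B (-4.05, SE 1.0, adjusted p = 0.00637). The pollen wall and tapetum products had 7 of 20 higher and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 0.0135 with the preset and adjusted p = 0.553 with an estimated correlation, while with repeated rows read back 7 of 22 were higher and 1 lower (adjusted p = 0.0504 with the preset and 0.743 with an estimated correlation)). The cold-protective proteins had 0 of 9 higher and 7 lower (0 and 8 adjusted over the list alone; adjusted p = 4.16e-05 with the preset and adjusted p = 0.407 with an estimated correlation). The abscisic acid genes had 0 of 8 higher and 5 lower (0 and 5 adjusted over the list alone; adjusted p = 0.00188 with the preset and adjusted p = 0.407 with an estimated correlation). In Lambayeque1, 5122 of 22495 genes passed the adjusted threshold, 2537 higher and 2585 lower (2926 and 2535 with quantile normalization), and 2740 had a log2 fold of at least 1. OsC6 lost the call at adjusted p = 0.0608 with no filter and 0.0542 with only the compared groups in the fit.

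The calls of different lines overlapped, OsC4 and RAB16A being among the shared genes. In all 4 lines 443 genes were higher and 521 lower, against 3.47 and 3.84 for independent lists, and 1590 were called in the same direction in 3 lines. Between pairs of lines the shared calls per direction were 3.12 to 4.54 times the number for independent lists. The lines share no library, but their tests share 1 estimate of spread per gene, taken from all 24 libraries. Genes of low spread can thus be called together in several lines, so the number for independent lists is not an exact reference. With only the compared groups, and so fewer libraries, in each fit, 359 genes were called in 4 lines, against 964 in the main fit. Across genes, which are not independent replicates, Pearson's r of the log2 changes ran from 0.51 (Nipponbare and PL9) to 0.72 (Nipponbare and Lambayeque1), and Spearman's rho from 0.47 to 0.65. The genes called in 4 lines numbered 613 without PL9 control replicate 2, against 964 with all libraries.

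The next question was whether lines differed in their response. The small heat shock gene HSP17.4 had the smallest p of the named genes, with log2 changes of -2.88 in Nipponbare, -0.62 in Sasanishiki, -4.26 in PL9 and -5.08 in Lambayeque1 (adjusted p = 0.00374, moderated F test). PAL, of the phenylpropanoid pathway, had log2 changes of -3.04 in Nipponbare, -1.59 in Sasanishiki, -0.15 in PL9 and -1.31 in Lambayeque1 (adjusted p = 0.00491), and the clock gene OsLUX of 2.91 in Nipponbare, 0.32 in Sasanishiki, 0.89 in PL9 and 3.29 in Lambayeque1 (adjusted p = 0.00932). The aquaporin gene PIP1-2 had log2 changes of -0.90 in Nipponbare, -0.88 in Sasanishiki, -0.14 in PL9 and -2.16 in Lambayeque1 (adjusted p = 0.00794). With 1 library left out, the Sasanishiki change of HSP17.4 ran from -1.0 to -0.38, and the PL9 changes of PAL and PIP1-2 from -0.40 to 0.01 and from -0.33 to 0.04. The OsLUX change was 0.23 in PL9 without cold replicate 2, and -0.07 or -0.09 in Sasanishiki without cold or control replicate 3. TIFY10B, 4CL3, HSP81-1, SAPK4, HSP16.9B and OsABA1 also differed between lines, with adjusted p = 0.0125, 0.0128, 0.0141, 0.0154, 0.0193 and 0.0198. OsC4 did not pass this test (adjusted p = 0.112), nor did CYP703A3 (adjusted p = 0.115) or RAB16A (adjusted p = 0.398). In all, 1659 genes differed in response between any lines. The count was 1063 without Sasanishiki cold replicate 1. PAL lost the call at adjusted p = 0.215 with pseudocount 0.1, and PIP1-2 at 0.0804 with quantile normalization, and SAPK4 at 0.0774 with quantile normalization.

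The gene examples for the pairs of lines were chosen after their values were seen. Between Sasanishiki and Nipponbare, the response of 1237 genes differed, 737 with a higher and 500 with a lower log2 change in the former. For OsLUX the difference was -2.59 (SE 0.63, adjusted p = 0.0207), and for CYP703A3 it was 6.31 (SE 2.08, adjusted p = 0.0821). With quantile normalization the split was 649 higher and 668 lower. The count was 682 without Nipponbare control replicate 1, 742 without Nipponbare cold replicate 1, 811 without Nipponbare cold replicate 3, 682 without Sasanishiki cold replicate 1, 718 without Sasanishiki cold replicate 3. Between PL9 and Nipponbare, the response of 976 genes differed, 661 with a higher and 315 with a lower log2 change in the former. For PAL the difference was 2.89 (SE 0.46, adjusted p = 0.00148), and for PIP1-2 it was 0.76 (SE 0.35, adjusted p = 0.225). With quantile normalization the split was 635 higher and 537 lower. The count was 508 without Nipponbare control replicate 1, 608 without Nipponbare cold replicate 1, 515 without PL9 control replicate 1, 1836 without PL9 cold replicate 1, 607 without PL9 cold replicate 3. Between Lambayeque1 and Nipponbare, the response of 137 genes differed, 88 with a higher and 49 with a lower log2 change in the former. For HSP17.4 the difference was -2.20 (SE 0.74, adjusted p = 0.208), and for PIP1-2 it was -1.25 (SE 0.35, adjusted p = 0.117). The count was 78 without Nipponbare control replicate 1, 90 without Nipponbare cold replicate 3, 83 without Lambayeque1 control replicate 3.

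Between PL9 and Sasanishiki, the response of 329 genes differed, 165 with a higher and 164 with a lower log2 change in the former (152 and 158 with quantile normalization). For HSP17.4 the difference was -3.64 (SE 0.74, adjusted p = 0.016), and for PAL it was 1.43 (SE 0.46, adjusted p = 0.137). The count was 152 without Sasanishiki control replicate 1, 955 without Sasanishiki control replicate 3, 141 without Sasanishiki cold replicate 1, 172 without Sasanishiki cold replicate 3, 157 without PL9 control replicate 1, 580 without PL9 cold replicate 1, 198 without PL9 cold replicate 3. Between Lambayeque1 and Sasanishiki, the response of 727 genes differed, 322 with a higher and 405 with a lower log2 change in the former. For HSP17.4 the difference was -4.45 (SE 0.74, adjusted p = 0.00251), and for OsLUX it was 2.97 (SE 0.63, adjusted p = 0.0128). The count was 452 without Sasanishiki control replicate 1, 1288 without Sasanishiki control replicate 3, 375 without Sasanishiki cold replicate 1, 482 without Sasanishiki cold replicate 2, 482 without Lambayeque1 cold replicate 2, 396 without Lambayeque1 cold replicate 3. Between Lambayeque1 and PL9, the response of 218 genes differed, 73 with a higher and 145 with a lower log2 change in the former. For PIP1-2 the difference was -2.02 (SE 0.35, adjusted p = 0.00849), and for OsLUX it was 2.41 (SE 0.63, adjusted p = 0.074). The count was 84 without PL9 control replicate 1, 126 without PL9 control replicate 2, 605 without PL9 cold replicate 1, 100 without PL9 cold replicate 3, 122 without Lambayeque1 control replicate 1, 86 without Lambayeque1 control replicate 2, 144 without Lambayeque1 cold replicate 1, 103 without Lambayeque1 cold replicate 2, 81 without Lambayeque1 cold replicate 3.

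Untreated anthers of the lines also differed. Against Nipponbare, untreated Sasanishiki had more OsABA8ox2, a gene of abscisic acid breakdown, and CIN3, and less of the tapetum genes CYP703A3 and OsC4, with log2 differences of OsABA8ox2 (3.06, SE 0.49, adjusted p = 6.35e-05), CIN3 (2.66, SE 0.60, adjusted p = 0.0016), CYP703A3 (-7.60, SE 1.47, adjusted p = 3.92e-04) and OsC4 (-6.72, SE 0.84, adjusted p = 3.21e-06). Untreated PL9 had more RAB16A and OsKAO and less CYP703A3 and OsAP25 than Nipponbare, with log2 differences of RAB16A (5.42, SE 1.41, adjusted p = 0.00669), OsKAO (4.44, SE 0.97, adjusted p = 0.00197), CYP703A3 (-7.63, SE 1.47, adjusted p = 6.96e-04) and OsAP25 (-5.88, SE 1.31, adjusted p = 0.00228). Untreated Lambayeque1 had more of the heat shock genes HSP16.9B and HSP18.1 and less OsC4 and OsCP1 than Nipponbare, with log2 differences of HSP16.9B (2.34, SE 0.67, adjusted p = 0.0346), HSP18.1 (2.14, SE 0.51, adjusted p = 0.0128), OsC4 (-3.73, SE 0.84, adjusted p = 0.00881) and OsCP1 (-2.70, SE 0.76, adjusted p = 0.0324). Between the other lines, HSP18.1 and HSP17.4 were higher in PL9 than in Sasanishiki (3.35 and 3.04) and HSP16.9B and SAPK5 lower (-5.77 and -1.79). Lambayeque1 had more HSP18.0 and HSP17.4 (5.10 and 4.60) and less CIN3 and CYCB2-1 (-2.69 and -2.05) than Sasanishiki, and more HSP16.9B and PIP2-4 (5.67 and 4.00) and less TIFY11A and OsTPP2 (-1.0 and -0.87) than PL9. In all, 11563 genes differed between any untreated lines. Sasanishiki and Nipponbare differed in 9013 genes, 3778 higher and 5235 lower in the former, and with quantile normalization 5422 higher and 4193 lower. PL9 and Nipponbare differed in 7191 genes, 3010 higher and 4181 lower in the former, and with quantile normalization 4492 higher and 3420 lower. Lambayeque1 and Nipponbare differed in 2018 genes, 790 higher and 1228 lower in the former. The count was 894 without Nipponbare control replicate 1, 1232 without Lambayeque1 control replicate 1, 1096 without Lambayeque1 control replicate 3. PL9 and Sasanishiki differed in 5241 genes, 2893 higher and 2348 lower in the former. Lambayeque1 and Sasanishiki differed in 7469 genes, 4165 higher and 3304 lower in the former, and with quantile normalization 3543 higher and 4385 lower. Lambayeque1 and PL9 differed in 2947 genes, 1864 higher and 1083 lower in the former, and with quantile normalization 1700 higher and 1661 lower. The count was 1817 without PL9 control replicate 1, 1866 without Lambayeque1 control replicate 2.

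CIN3, between untreated Sasanishiki and Nipponbare, lost the call at adjusted p = 0.0553 with only the compared groups in the fit. HSP16.9B, between untreated Lambayeque1 and Nipponbare, lost the call at adjusted p = 0.0653 with pseudocount 0.1, 0.113 without Nipponbare control replicate 1, 0.0917 without Nipponbare control replicate 2, 0.0598 without Nipponbare control replicate 3, 0.103 without Lambayeque1 control replicate 2 and 0.141 without Lambayeque1 control replicate 3, and OsCP1 at 0.0534 with pseudocount 0.1, 0.0878 without Nipponbare control replicate 1, 0.0616 without Nipponbare control replicate 2, 0.102 without Nipponbare control replicate 3, 0.0656 without Lambayeque1 control replicate 1, 0.0908 without Lambayeque1 control replicate 2 and 0.0872 without Lambayeque1 control replicate 3, and HSP18.1 at 0.0567 without Nipponbare control replicate 2 and 0.057 without Lambayeque1 control replicate 2, and OsC4 at 0.0597 without Lambayeque1 control replicate 3. CIN3, between untreated Lambayeque1 and Sasanishiki, lost the call at adjusted p = 0.0689 with only the compared groups in the fit, and CYCB2-1 at 0.0511 with only the compared groups in the fit, 0.0535 without Sasanishiki control replicate 1, 0.155 without Sasanishiki control replicate 3, 0.0768 without Lambayeque1 control replicate 1, 0.0699 without Lambayeque1 control replicate 2 and 0.0504 without Lambayeque1 control replicate 3. OsTPP2, between untreated Lambayeque1 and PL9, lost the call at adjusted p = 0.0783 without PL9 control replicate 1, 0.0502 without PL9 control replicate 2, 0.0527 without Lambayeque1 control replicate 1 and 0.0948 without Lambayeque1 control replicate 2.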

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

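Chosen only after results had been seen were the tests of stage and of floret tissue, the splits with line means removed, and the values that compare PL9 cold library 2 with other libraries or leave it out. The tests between lines drew attention to 1659 genes whose response differed between any lines, and to 1237, 976, 137, 329, 727 and 218 genes in the pairs in the order Sasanishiki, PL9 and Lambayeque1 against Nipponbare, PL9 and Lambayeque1 against Sasanishiki, and Lambayeque1 against PL9. Named genes among them were HSP17.4 (adjusted p = 0.00374), PAL (0.00491), PIP1-2 (0.00794), OsLUX (0.00932), TIFY10B (0.0125), 4CL3 (0.0128), HSP81-1 (0.0141), SAPK4 (0.0154), HSP16.9B (0.0193) and OsABA1 (0.0198), by the moderated F test of limma. The repeated identifiers, outside the main measurement, held a signal when read back, as 2789 of 5160 such identifiers passed the threshold for the averaged response, 1394 higher and 1395 lower.

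Between cold groups the lines differed less than between untreated groups. The root mean square log2 difference over genes was smaller after cold in 6 of the 6 line pairs, as 0.70 against 1.06 for PL9 and Nipponbare, the largest drop (0.86 without PL9 cold library 2, which lies near the Nipponbare cold libraries), but only 1.08 against 1.12 for Sasanishiki and Lambayeque1. A hypothesis is that differences in response between lines may in part reflect different untreated states. What made the untreated states differ was not tested, and a genetic difference in the response itself stays open.

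Averaged over lines, 13 of 20 measured pollen wall and tapetum products rose after cold and 1 fell, a list call that was lost with an estimated correlation. Library scaling as the whole cause is argued against by the list's median log2 change, which was 2.07 with quantile normalization. Median-of-ratios rescaling (2.23) could move it little, because the libraries' median log2 ratios already lay between -0.01 and 0.04, so it does not bear on this. Dilution of untreated anthers by other floret tissue is argued against by the 4 carpel and outer floret markers. Their median change was 0.22 and the lowest -0.30. With repeated rows read back, 6 markers had a median of -0.14 and a lowest change of -0.37. All these values lay above the bound of -1 set for the median. A stage difference between untreated and cold anthers may also give such a rise. The correlation over genes chosen to test it, of the Lambayeque1 response with the difference of untreated Nipponbare and Sasanishiki, was 0.0525. It lay below the bound of 0.1 set against a stage difference, the bound set for one being 0.2. The 12 such correlations ran from -0.10 to 0.40. Those of the PL9 response with untreated Nipponbare minus Lambayeque1 (0.40) and minus Sasanishiki (0.32) lay above 0.2, and the rest below it. The bounds had been set only for the chosen correlation. Stage still cannot be told apart from cold, because the labels give no stage or collection time for untreated anthers. Untreated Nipponbare and Sasanishiki also need not differ in stage. A response to cold itself stays open too.

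PL9 cold library 2 had the lowest correlation with its own group (0.891, against 0.905 for library 1), and its highest correlation with any library was with Nipponbare cold library 2 (0.937, against 0.927 and 0.854 with PL9 cold libraries 3 and 1). RNA of another line in it is argued against by genes at 5 or more in all 6 libraries of another line and below 0.5 in the other PL9 libraries, whose highest median in this library was 0% of that line's level over 42, 61 and 47 genes for the 3 lines. Of the 42 genes of Nipponbare, 4 reached 10% or more of its level, against at most 1 in the other PL9 libraries. Its difference from the other PL9 cold libraries correlated over genes with the response of the 3 other lines at 0.15, against -0.26 and 0.17 for PL9 cold libraries 1 and 3 treated alike, so a stronger response in this library cannot be told apart from other causes, and no other biological explanation was tested.

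Libraries were also regrouped. For the response in 1 line and for each untreated pair, the 6 libraries allow 10 splits, too few for a share under 0.05; the real split alone (1 of 10) reached its count in each. The real counts and the highest of the other splits were 5944 and 3 for Nipponbare, 5638 and 80 for Sasanishiki, 3897 and 66 for PL9, 5122 and 1 for Lambayeque1, and for untreated pairs 9013 and 105 for Sasanishiki against Nipponbare, 7191 and 2 for PL9 against Nipponbare, 2018 and 8 for Lambayeque1 against Nipponbare, 5241 and 58 for PL9 against Sasanishiki, 7469 and 6 for Lambayeque1 against Sasanishiki, 2947 and 6 for Lambayeque1 against PL9. Chance regrouping of treatments within lines can be excluded for the averaged response (11373 genes, at most 490 in the other 99 of 100 drawn splits). Of the list tests, 28 passed with the preset correlation, against at most 23 in those other splits, and 0 with an estimated one. With up to 23 passing in a regrouped split, the pass of a single list with the preset does not exclude chance. For genes called in 4 lines (964 against 0) these splits add nothing, since regrouped lines call too few genes to overlap. Exchanging line labels within treatments excludes chance for differences between any untreated lines (11563 against 4193). For differences in response between any lines, the real count was also above that of the other splits (1659 against at most 1097). Untreated lines already differ, and an exchange mixes that difference into the response. This test therefore cannot exclude chance for the response itself. For pairs the exchange did not set the real count apart. For Sasanishiki against Nipponbare, 15 of 100 splits reached the 1237 genes, the highest other calling 11173. For PL9 against Nipponbare, 11 of 100 splits reached the 976 genes, the highest other calling 7576. For Lambayeque1 against Nipponbare, 8 of 100 splits reached the 137 genes, the highest other calling 1376. For PL9 against Sasanishiki, 14 of 100 splits reached the 329 genes, the highest other calling 6438. For Lambayeque1 against Sasanishiki, 9 of 100 splits reached the 727 genes, the highest other calling 9332. For Lambayeque1 against PL9, 11 of 100 splits reached the 218 genes, the highest other calling 3955. Splits that call several times the real count point to a structure of the samples, since exchanging labels in 1 treatment puts the difference between lines into the comparison. With each line's mean removed first, the highest other splits called 227, 624, 11, 292, 177 and 330 genes in that order. Of 100 splits, 2 reached the real count for the last pair and 1 for each of the others; for any lines it was 1 of 100, with 2 genes at most. For the pairs, chance was argued against only by this later test. That test was chosen after the first splits had been seen and used the true lines to remove the means. Chance is therefore not excluded for the pairs, nor for the response between any lines.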

How the results depend on the processing

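Chosen after the data were seen were the repeated rows read back and the lists of checked names. Summing the repeated rows was the plan and became an alternative then. The estimated correlation was part of the design. Counts are of genes past the threshold, and of list tests. A pair of lines named with cold stands for the difference of their responses. The counts below moved by over 1.5 times, and for each the cause was not tested unless named. With pseudocount 0.1: cold PL9 against Nipponbare 634, cold Lambayeque1 against Nipponbare 48, cold Lambayeque1 against PL9 140. With pseudocount 5: cold Lambayeque1 against Nipponbare 281. With no filter: cold Lambayeque1 against Nipponbare 216. With a filter of at least 5 in 3 libraries: cold between any lines 1048, cold Sasanishiki against Nipponbare 743, cold PL9 against Nipponbare 584, cold Lambayeque1 against Nipponbare 48, cold PL9 against Sasanishiki 189, cold Lambayeque1 against Sasanishiki 478, untreated Lambayeque1 against Nipponbare 1276. With the highest row per gene: cold between any lines 3172, cold Sasanishiki against Nipponbare 2485, cold PL9 against Nipponbare 2238, cold Lambayeque1 against Nipponbare 1198, cold PL9 against Sasanishiki 1618, cold Lambayeque1 against Sasanishiki 2018, cold Lambayeque1 against PL9 1409, untreated Lambayeque1 against Nipponbare 4407, untreated PL9 against Sasanishiki 8668, untreated Lambayeque1 against PL9 6290, gene list tests 15. With only the compared groups in the fit: cold Sasanishiki 3103, cold PL9 1353, cold PL9 against Sasanishiki 86, cold Lambayeque1 against PL9 92, untreated PL9 against Sasanishiki 3305, untreated Lambayeque1 against Sasanishiki 4357, overlap 359. With array weights, whose iteration stopped before its tolerance was reached: cold Nipponbare 9345, cold Sasanishiki 9173, cold PL9 1561, cold Lambayeque1 10349, cold between any lines 5906, cold Sasanishiki against Nipponbare 4008, cold Lambayeque1 against Nipponbare 1797, cold PL9 against Sasanishiki 496, cold Lambayeque1 against Sasanishiki 4827, untreated PL9 against Nipponbare 11445, untreated Lambayeque1 against Nipponbare 8219, untreated Lambayeque1 against PL9 7066. With a log2 fold minimum of 1: cold Nipponbare 3178, cold Sasanishiki 3045, cold PL9 2212, cold Lambayeque1 2740, cold average 2645, untreated Sasanishiki against Nipponbare 5486, untreated PL9 against Nipponbare 4182, untreated Lambayeque1 against Nipponbare 1310, untreated PL9 against Sasanishiki 3267, untreated Lambayeque1 against Sasanishiki 4307, untreated Lambayeque1 against PL9 1770, overlap 512. With repeated rows summed: cold between any lines 3235, cold Sasanishiki against Nipponbare 2568, cold PL9 against Nipponbare 2174, cold Lambayeque1 against Nipponbare 1158, cold PL9 against Sasanishiki 1516, cold Lambayeque1 against Sasanishiki 2033, cold Lambayeque1 against PL9 1304, untreated Lambayeque1 against Nipponbare 4809, untreated PL9 against Sasanishiki 8790, untreated Lambayeque1 against PL9 6771, gene list tests 17. With estimated correlation: gene list tests 0. Summed or highest repeated rows carry copied values over neighbouring libraries, which lowers their spread by construction. Read back, 32 list tests passed with the preset and none with an estimated correlation. Calls lost then, with adjusted p, were pollen wall and tapetum products Nipponbare 0.0664, pollen wall and tapetum products Lambayeque1 0.0504, starch and sucrose enzymes PL9 0.432, starch and sucrose enzymes averaged over lines 0.352, and calls gained were cold-responsive transcription factors Nipponbare 0.0301, cold-responsive transcription factors averaged over lines 0.0352, cold-protective proteins Nipponbare 0.00543, circadian clock Sasanishiki 0.0286, stamen identity Lambayeque1 0.0352, photosynthesis and chlorophyll Nipponbare 0.0104, photosynthesis and chlorophyll PL9 0.00528, jasmonate Nipponbare 0.0345. No count moved by over 1.5 times then, nor under median-of-ratios rescaling, quantile normalization or lists of checked names. The fold minimum was not applied to list tests and tests between any lines, which have no fold per gene. With 1 library left out, counts ranged as follows, the libraries that moved them by over 1.5 times in parentheses. Cold Sasanishiki against Nipponbare 682 to 1429 (Nipponbare control 1 682, Nipponbare cold 1 742, Nipponbare cold 3 811, Sasanishiki cold 1 682, Sasanishiki cold 3 718). Cold PL9 against Nipponbare 508 to 1836 (Nipponbare control 1 508, Nipponbare cold 1 608, PL9 control 1 515, PL9 cold 1 1836, PL9 cold 3 607). Cold Lambayeque1 against Nipponbare 78 to 185 (Nipponbare control 1 78, Nipponbare cold 3 90, Lambayeque1 control 3 83). Untreated Lambayeque1 against Nipponbare 894 to 1446 (Nipponbare control 1 894, Lambayeque1 control 1 1232, Lambayeque1 control 3 1096). Cold Sasanishiki 3438 to 5707 (Sasanishiki control 1 3438). Cold PL9 against Sasanishiki 141 to 955 (Sasanishiki control 1 152, Sasanishiki control 3 955, Sasanishiki cold 1 141, Sasanishiki cold 3 172, PL9 control 1 157, PL9 cold 1 580, PL9 cold 3 198). Cold Lambayeque1 against Sasanishiki 375 to 1288 (Sasanishiki control 1 452, Sasanishiki control 3 1288, Sasanishiki cold 1 375, Sasanishiki cold 2 482, Lambayeque1 cold 2 482, Lambayeque1 cold 3 396). Cold between any lines 1063 to 2452 (Sasanishiki cold 1 1063). Cold PL9 1811 to 4788 (PL9 control 1 1811, PL9 control 2 2217, PL9 cold 2 2095, PL9 cold 3 2109). Cold Lambayeque1 against PL9 81 to 605 (PL9 control 1 84, PL9 control 2 126, PL9 cold 1 605, PL9 cold 3 100, Lambayeque1 control 1 122, Lambayeque1 control 2 86, Lambayeque1 cold 1 144, Lambayeque1 cold 2 103, Lambayeque1 cold 3 81). Untreated Lambayeque1 against PL9 1817 to 2580 (PL9 control 1 1817, Lambayeque1 control 2 1866). Overlap 613 to 1024 (PL9 control 2 613). Quantile normalization moved the median log2 change of all genes by 0.17 for untreated Sasanishiki against Nipponbare, 0.13 for untreated PL9 against Nipponbare, -0.12 for untreated Lambayeque1 against Sasanishiki, and no named gene past the threshold reversed under it. By the rule that every pair exceeds 0.1, the replicate numbers do not pair the libraries: 2 of 12 same-numbered pairs had deviations correlated above 0.1 (-0.39 to 0.12), and 3 of 12 control libraries correlated best with their own number. These were the PL9 libraries, whose same-numbered pairs had 0.08 to 0.12 and the other pairs -0.10 to -0.01, a hint from the data that falls short of the rule. With the replicate block, counts were cold Nipponbare 5668, cold Sasanishiki 5375, cold PL9 3649, cold Lambayeque1 4885, cold average 11112, cold between any lines 1399, untreated lines differ 11125, overlap 913, gene list tests 28, no count moved by over 1.5 times, and 2 named results lost the call. Of 144 results of named genes past the threshold, 25 lost the call in some setting, 20 of them with all libraries in, and 0 reversed. The averaged changes of OsPRR1, PORA, DL and OsKAO lost it most often. Depth is unknown, so what it limits cannot be given.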

Other observations

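Lists written after the files were opened gave further values for the averaged response. In heat shock proteins and factors, 1 of 16 measured members rose, 10 fell and 5 did not pass the test, with adjusted p = 0.0011 with the preset and adjusted p = 0.407 with an estimated correlation. HSFA6A, HSP17.4 and HSFB2B fell by 2.46, 3.21 and 4.20 on the log2 scale. In starch and sucrose enzymes, 5 of 8 measured members rose, 0 fell and 3 did not pass the test, with adjusted p = 0.0467 with the preset and adjusted p = 0.407 with an estimated correlation, while with repeated rows read back 8 of 17 were higher and 4 lower (adjusted p = 0.352 with the preset and 0.688 with an estimated correlation). SSI rose (0.58) beside ISA1 and CIN2. In photosynthesis and chlorophyll genes, 3 of 5 measured members rose, 0 fell and 2 did not pass the test, with adjusted p = 0.193 with the preset and adjusted p = 0.553 with an estimated correlation, while with repeated rows read back 8 of 14 were higher and 3 lower. PETE and CHLI rose (2.09 and 0.66). In jasmonate genes, 2 of 11 measured members rose, 5 fell and 4 did not pass the test, with adjusted p = 0.498 with the preset and adjusted p = 0.727 with an estimated correlation. TIFY11D and TIFY11C, repressors of jasmonate signalling, fell by 2.39 and 1.21, while both COI1 genes rose. In stress signalling and factors, 1 of 15 measured members rose, 6 fell and 8 did not pass the test, with adjusted p = 0.108 with the preset and adjusted p = 0.561 with an estimated correlation. SNAC2 and BZIP23 fell by 2.80 and 1.47.

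In aquaporins, 0 of 4 measured members rose, 3 fell and 1 did not pass the test, with adjusted p = 0.274 with the preset and adjusted p = 0.553 with an estimated correlation, while with repeated rows read back 2 of 11 were higher and 5 lower. In cell cycle and replication, 2 of 10 measured members rose, 0 fell and 8 did not pass the test, with adjusted p = 0.604 with the preset and adjusted p = 0.821 with an estimated correlation, while with repeated rows read back 2 of 15 were higher and 2 lower. In cellulose and secondary wall, 1 of 4 measured members rose, 3 fell and 0 did not pass the test, with adjusted p = 0.323 with the preset and adjusted p = 0.553 with an estimated correlation. CESA9 and CESA7 fell by 1.99 and 1.65 and 4CL3 rose (1.33). In cytokinin, auxin and brassinosteroid genes, 2 of 7 measured members rose, 3 fell and 2 did not pass the test, with adjusted p = 0.619 with the preset and adjusted p = 0.815 with an estimated correlation. In desaturases and redox, 2 of 6 measured members rose, 4 fell and 0 did not pass the test, with adjusted p = 0.634 with the preset and adjusted p = 0.815 with an estimated correlation. APX8 fell by 1.01 and APX5 rose (0.83). Within single lines, heat shock proteins and factors passed with the preset in each (adjusted p = 0.0305 in Nipponbare, adjusted p = 0.00517 in Sasanishiki, adjusted p = 0.00339 in PL9, adjusted p = 1.51e-04 in Lambayeque1), as did, with the estimated correlation after each, starch and sucrose enzymes in PL9 (adjusted p = 0.0297 and 0.407, while with repeated rows read back 5 of 17 were higher and 2 lower (adjusted p = 0.432 with the preset and 0.743 with an estimated correlation)), stress signalling and factors in Sasanishiki (adjusted p = 0.00517 and 0.407, while with repeated rows read back 2 of 23 were higher and 10 lower), aquaporins in Lambayeque1 (adjusted p = 0.0345 and 0.407) and cell cycle and replication in Nipponbare (adjusted p = 0.018 and 0.407, while with repeated rows read back 5 of 15 were higher and 1 lower). None of these lists passed with an estimated correlation.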
